A study of Dreissena polymorpha with 12 samples.

How the data were processed

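Gene expression was measured in zebra mussels (Dreissena polymorpha, a freshwater bivalve) collected in spring at 6 sites. There were 5 sites along the Ebro River (Mequinenza, Faio, Riba Roja, Flix Reservoir and Flix Factory) and 1 dam, Sitjar, 200 km away. Each site had 2 arrays, and each array held a pool of 5 individuals. The labels give gills as the tissue, while the collection protocol speaks of part of the body of each individual, so the tissue in the pools is not settled. The 2 pools of a site were taken as separate samples, as the labels number them. Nothing states how the individuals were divided. Each pool had 1 array, so the p-values measure the spread between these pools and between their arrays together. That spread includes the slide described below, except where the slide is a block.

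Per the labels' protocols, 500 ng of total RNA per pool was amplified and labelled with Cy3 and hybridised to a one-colour Agilent array. The spot intensity values were made by Agilent Feature Extraction, version 10.5.1.1 per the file headers; the submitters' processing notes name version 9.5. The processed signal used here is a linear intensity, background-subtracted and detrended within the array and not scaled between arrays, per the file headers and columns. The flags for spots well above background, saturated spots and outlier spots, coded 0 or 1, were also deposited with each array and are the scanner software's own calls. The authors' deposited value table holds log2 values of the same arrays. Against the log2 processed signal of the same spots, its columns had correlations of 0.985 to 0.9999 and slopes of 0.93 to 1.20, so its scale is log2. Its medians, for replicates 1 and 2 in turn, were 2.93 and 3.13 for Riba Roja, 2.99 and 3.06 for Flix Reservoir, 3.01 and 3.09 for Flix Factory, 2.99 and 3.26 for Mequinenza, 2.99 and 3.01 for Faio, and 2.93 and 2.94 for Sitjar. How the authors centred or normalised that table is not given in the sources used here, and it served only as an alternative. It held 14996 spots, and 212 non-control spots of the array were not in it.

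An array had 15744 spots, of which 536 were controls and were left out. The other 15208 spots held 13654 probes for 3541 named sequences. Outlier-flagged spots were left out, log2 signals of the copies of a probe were averaged, and no spot was saturated. A probe with copies counted as well above background where more than 0.5 of its copies were. Between 22.5% and 34.8% of probes were well above background on an array. Since this is under 50%, each array was scaled by subtracting the 75th percentile of log2 signal over the 2806 probes well above background on all 12 arrays, and the percentile over all probes was an alternative. The design fixed beforehand had named the 75th percentile without that restriction. The 4305 probes (31.5%) well above background on both arrays of at least 1 site were tested. This filter used the site labels, so a probe could enter through 1 bright site alone. The adjusted p of such a probe may be too small. They covered 1845 sequences, and 1177 of these had at least 2 tested probes; 6851 probes were above background on no array. Where every array of a group was below background, the fold is given as a lower limit: the bright group's mean against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal. Arrays of the bright group that were not well above background enter as measured, so a limit with such arrays is not strict.

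All 12 arrays entered 1 limma fit (version 3.58.1, R 4.3.3) with 6 site means. Moderated F tests compared the 6 sites and the 5 Ebro sites. Contrasts compared the Ebro mean with Sitjar, each Ebro site with the mean of the other 4, and Flix Factory with Flix Reservoir. Every adjusted p is limma's, with Benjamini-Hochberg adjustment over the tested probes, and the threshold was 0.05. The number of arrays limits the precision.

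Per the file headers, all first replicates lay on slide 1 and all second replicates on slide 2, each slide with its own scan, so that the replicate number, the slide and the scan are one factor. Each site also occupied the same position on both slides, so site and array position cannot be told apart. Whether the replicate numbers pair the samples was checked from each array's deviation from its site mean. Over the 15 pairs of sites, arrays with the same number had correlated deviations (r across probes 0.30 to 0.72, median 0.58), all over the limit of 0.1. The first principal component, with 39.7% of the variance, also separated the slides. The numbers were therefore taken to pair the samples, through the slide, and the fit with the slide as a block is given beside each result that it changes. Within a slide each site has a single array, so only differences are given per slide.

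The scripts were tested on simulated data made from 4249 probes over 10 rounds, with 200 probes changed in 1 site in each. The simulated arrays had each probe's mean and slide difference, and normal residuals with the probe's spread from the fit with the block. That spread was equal on all arrays, and no other site difference was put in. The real arrays were less even, so the shares below may not hold for them. For Ebro sites against Sitjar, the fit without the block found 3.2% of 2-fold and 46.1% of 4-fold changes, and the fit with the block found 34.9% and 84.5%. For Flix Factory against the other Ebro sites these were 1.4% and 43.6%, and 31.4% and 83%. False calls made up 1.0% to 5.9% of the calls.

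The files name probes by sequence accessions and give RXR, on 6 probes, as the only gene symbol. Of the sequence names, 0 matched the reference gene table (assembly UMN_Dpol_1.0). The gene lists and cell type markers fixed before the data were examined need gene descriptions, so they were not run. The rule for named genes was to take the probes past the threshold with the largest rises and falls that carry a gene name. With no names it was reduced to at most 2 probes per direction and contrast in the fit without the block. Apart from RXR, other probes and sequences named below were chosen after their values were seen, and each is said to be so.

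The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median scaling, the authors' values, 2 other filters on dim probes, the replicate and slide block, limma-trend, array weights, means per sequence, a threshold of 0.01, a minimum of 2-fold, fits on the compared arrays alone, the site as a random block, and each of the 12 arrays left out in turn. Normexp was run on the median spot signal in place of the planned mean spot signal, which is not among the columns used here. A common floor and combinations of the block with each alternative were chosen after seeing the data. So was the restriction of the scaling percentile to the 2806 probes. The percentile over all probes, listed only then as an alternative, lies closest to the design fixed beforehand.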

Results

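The series compared expression profiles of zebra mussels among 6 sampling sites, with 2 pools of 5 individuals per site and 1 one-colour array per pool. The share of probes well above background ranged from 22.5% on the second Mequinenza array to 34.8% on the first Sitjar array. It averaged 32.8% ± 1.32 (SD, n = 6 arrays) on slide 1 and 29.0% ± 4.10 (SD, n = 6 arrays) on slide 2. Copies of a probe on the same array had a median SD of 0.10 on the log2 scale (10 probes with 25 copies each). The 2 pools of a site differed more, with a median SD of 0.53, or 0.35 once the mean difference between the slides was removed.

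The largest source of variation was the slide. The first principal component held 39.7% of the variance and separated the 6 arrays of slide 1 from the 6 of slide 2. With the slide as a term in the limma fit, 1533 of the 4305 tested probes (35.6%) differed between slides, 564 higher and 969 lower on slide 2. The second component, with 20.6% of the variance, set single arrays apart, with Mequinenza replicate 2 at 34.4 and Faio replicate 1 at 20.9, against 8.8 and 2.1 for the other array of each site. The third component, with 12.6% of the variance, set both Sitjar arrays apart from the 10 Ebro arrays.

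**Figure D1:**
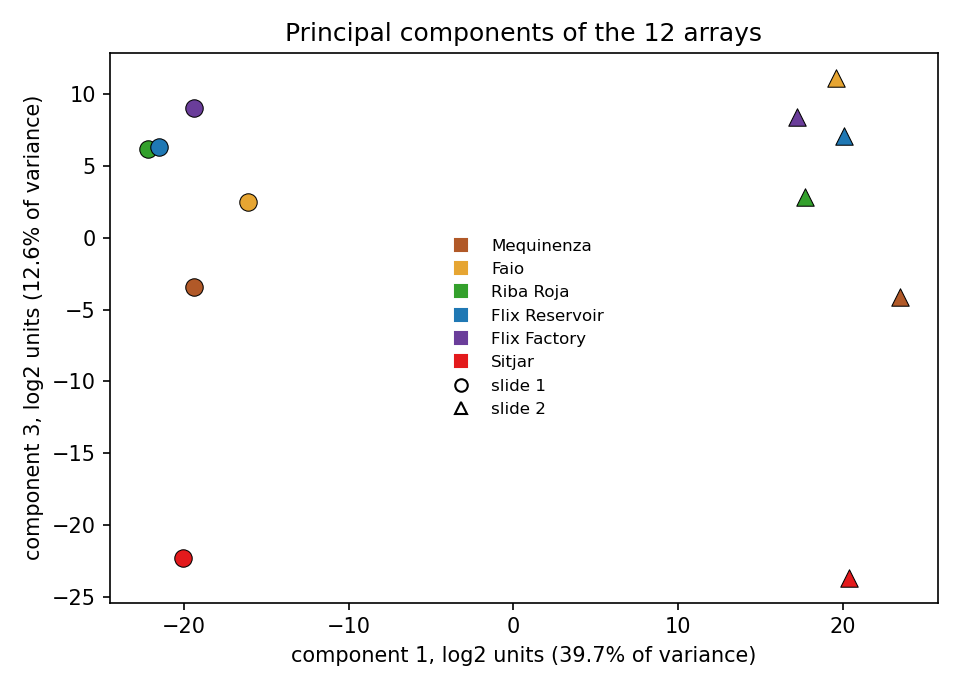
Scores of the 12 arrays on principal components 1 (horizontal, 39.7% of variance) and 3 (vertical, 12.6%), in log2 units, over the 2806 probes well above background on all arrays; colours are sites, circles slide 1 and triangles slide 2. The slides lie on opposite sides of component 1, and the Sitjar arrays lie at -22.26 and -23.66 on component 3, below all Ebro arrays (-4.14 to 11.13).

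The comparison of the Ebro with Sitjar asks how the river populations differ from a population outside the river. Probe CUST_1825_PI415929191 of sequence EY435800 was 8.44-fold lower in the Ebro than in Sitjar (log2 difference -3.08, SE 0.31, adjusted p = 0.0222). Its scaled log2 signal was -5.08 ± 0.38 (SD, n = 10) on the Ebro arrays and -2.01 ± 0.19 (SD, n = 2) on the Sitjar arrays, and it was well above background on all of them. Probe CUST_8173_PI415929191 of EY435040 was well above background on both Sitjar arrays and on none of the 10 Ebro arrays, so it was at least 2.19-fold lower in the Ebro (adjusted p = 0.0237). Probe CUST_11632_PI415929191 of AJ517516 was at least 3.82-fold higher in the Ebro if every Ebro signal is taken as measured (adjusted p = 0.0222). That is not a strict lower limit, because Mequinenza replicate 2 and Faio replicate 2 were not well above background. The probe was well above background on 8 of 10 Ebro arrays and on neither Sitjar array, and all 4 tested probes of AJ517516 had higher values in the Ebro. CUST_8173_PI415929191 and CUST_11632_PI415929191 thus entered the test only through sites where they were brighter, so their adjusted p may be too small. Without the filter on dim probes their limma adjusted p was 0.290, as was that of CUST_1825_PI415929191. With normexp the log2 difference was -0.11 for CUST_8173_PI415929191 and 1.45 for CUST_11632_PI415929191 (limma adjusted p = 0.912 and 0.185), and with a common floor neither could be measured. These 3 probes, 1 higher and 2 lower in the Ebro, were the calls of the limma fit without the slide, in which 576 of 4305 probes had an unadjusted p under 0.05. Each of the 3 differed in the same direction on both slides. Calls favour such probes, because each slide holds a single Sitjar array, so this is no separate support. The log2 differences on slides 1 and 2 were -2.88 and -3.27 for CUST_1825_PI415929191, -3.13 and -2.34 for CUST_8173_PI415929191, and 2.17 and 2.35 for CUST_11632_PI415929191.

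**Figure D2:**
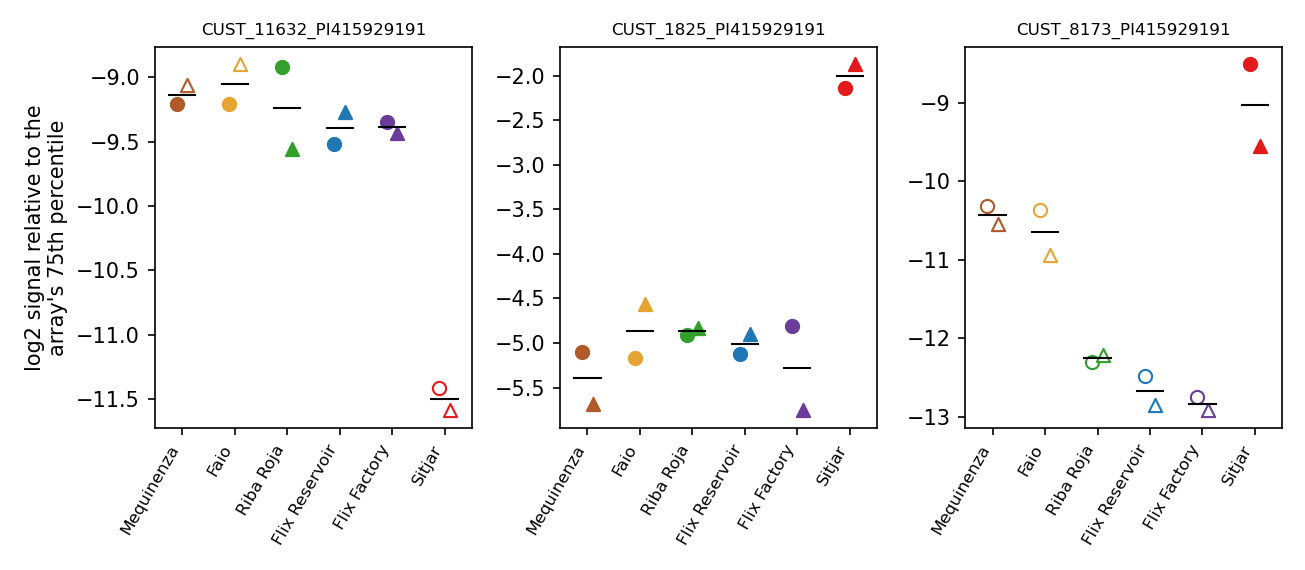
Scaled log2 signal (relative to the array's 75th percentile) of the 3 probes called between the Ebro sites and Sitjar, per array; circles are slide 1, triangles slide 2, filled symbols well above background, open symbols not, and bars the mean of the 2 arrays of a site. In CUST_1825_PI415929191 all arrays are filled and the 10 Ebro arrays lie below both Sitjar arrays; open symbols in the other panels have only an upper bound.

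With the slide as a block, 197 probes of 142 sequences differed between the Ebro sites and Sitjar, 158 higher and 39 lower in the Ebro, and 130 of them by at least 2-fold. The median absolute log2 difference of the 197 probes was 1.23. Of these probes, 142 were well above background on all 12 arrays, 7 on no Ebro array and 9 on neither Sitjar array. Of the 40 sequences with at least 2 called probes, 36 were higher and 4 lower in the Ebro, and none had calls in both directions. The 3 sequences with the most called probes, 4 each, are named here after their values were seen. AM503947 was 4.17 to 5.15-fold higher in the Ebro by its 4 tested probes; for CUST_7659_PI415929188 the log2 difference was 2.36 (SE 0.29, adjusted p = 0.0264 in the limma fit with the block). EY436722 was 1.75 to 2.58-fold higher by its 4 called probes, which were well above background on all 12 arrays. EY435186 was lower by its 4 tested probes, 2.37 to 2.78-fold; for CUST_2377_PI415929191 the log2 difference was -1.47 (SE 0.17, adjusted p = 0.0264 in the same fit). None of these 3 sequences passed the threshold without the block, where their smallest adjusted p from limma was 0.0802. All probes of the 3 sequences kept their direction under 5 other scalings, but not all kept their calls. EY436722 was called by 1 of its 5 tested probes under quantile normalization or with the authors' values and by 2 with the percentile over all probes, and its lowest log2 difference was 0.81 as reported and 0.27 under quantile normalization. EY435186 was called by 2 of 4 under normexp, with log2 differences of -0.60 to -0.88 against -1.24 to -1.47 as reported, and by 3 under quantile normalization or with the percentile over all probes. AM503947 kept all 4 calls.

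**Figure D3:**
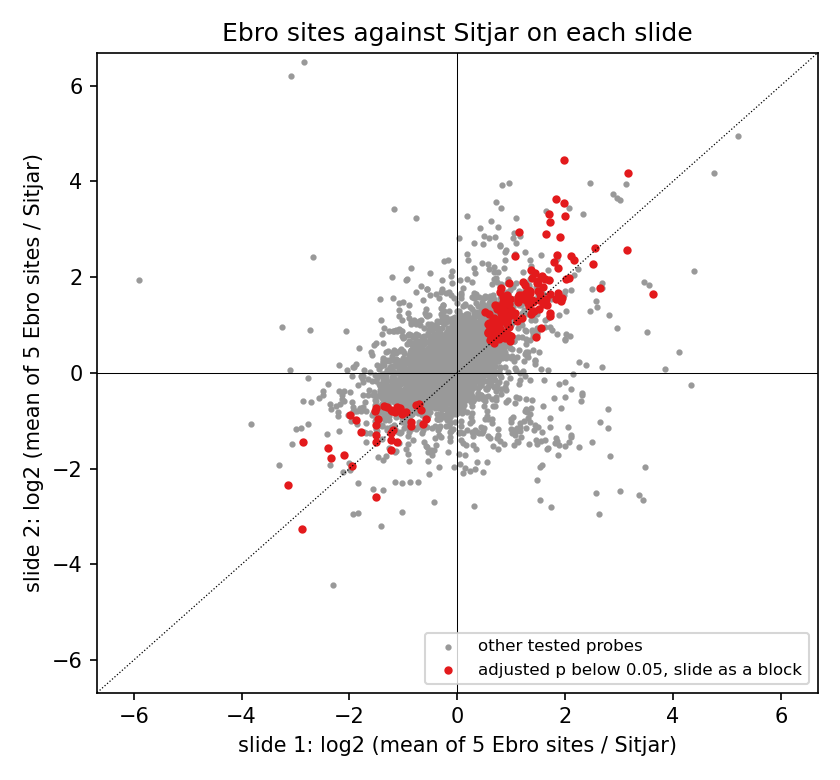
Log2 difference between the mean of the 5 Ebro sites and Sitjar for each tested probe on slide 1 (horizontal) and slide 2 (vertical); red points are the 197 probes with an adjusted p below 0.05 with the slide as a block (4 with a flagged spot are not drawn), grey points the other tested probes, and the dotted line marks equal values. The red points lie in the quadrants of equal sign, which calls favour because each slide holds a single Sitjar array.

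The count and its split between higher and lower probes depended on the scaling and on single arrays. Without the block, leaving out an array also leaves its site on 1 slide, so part of the slide difference enters the comparison. This holds for all such counts below. With the block, quantile normalization gave 106 higher and 69 lower, the authors' values 146 and 153, the percentile over all probes 142 and 115, and normexp 531 and 37. Without the block, the split of 1 higher and 2 lower became 1 and 6 under quantile normalization, 3 and 15 with the authors' values, 0 and 2 with median scaling or the percentile over all probes, and 0 and 1 under normexp. It leaned the other way over the probes well above background on all 12 arrays (13 higher and 2 lower) and with the site as a random block (52 and 20). The blocked count was 800 without Mequinenza replicate 1, 625 without Mequinenza replicate 2, 62 without Faio replicate 1, 9 and 6 without Flix Factory replicates 1 and 2, and 2 without either Riba Roja array. It was 0 without Faio replicate 2, either Flix Reservoir array or either Sitjar array, where the smallest adjusted p from limma lay between 0.0525 and 0.0727. The count without the block was 102, 9 and 5 without Mequinenza replicate 1, Mequinenza replicate 2 and Faio replicate 1. It was 1 without either Flix Factory array and 0 without any other array.

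Each Ebro site was then set against the other 4, to ask which site stands apart within the river. At Mequinenza, sequence AF508224 was higher by 2 probes that were well above background on all 12 arrays. Probe CUST_4_PI415924929 was 7.27-fold higher than at the other Ebro sites (log2 difference 2.86, SE 0.32, adjusted p = 0.0306), and CUST_68_PI415929191 was 7.04-fold higher (2.81, SE 0.34, adjusted p = 0.0342). For CUST_4_PI415924929 the scaled log2 signal was -0.41 ± 0.55 (SD, n = 2) at Mequinenza, -3.27 ± 0.80 (SD, n = 8) at the other Ebro sites and -3.33 ± 0.02 (SD, n = 2) at Sitjar. The other 3 probes of AF508224 did not pass the threshold, with log2 differences of 3.59, 2.29 and 0.15. The last of these, CUST_69_PI415929191, was the brightest, at 2.93 at Mequinenza and 2.78 at the other Ebro sites. With the block its SE was 0.18 (limma adjusted p = 0.703), so this probe showed no difference near the size of the called ones. The probes of this sequence thus disagreed, and whether its expression was higher at Mequinenza is not settled. AF508224 was singled out after its values were seen.

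By the naming rule, CUST_10688_PI415929191 of AM229758 was at least 3.43-fold higher at Mequinenza (adjusted p = 0.0389) and CUST_11404_PI415929191 of AM230162 at least 4.36-fold higher (adjusted p = 0.0306), since neither was well above background at the other Ebro sites. Both entered the test only through Mequinenza, so these adjusted p may be too small. Without the filter on dim probes both stayed called (limma adjusted p = 0.0318 for each), but the median log2 difference of all probes was then 0.74. CUST_7267_PI415929191 of EY436624 was at least 3.38-fold lower (adjusted p = 0.0378) and CUST_3524_PI415929191 of EY435375 at least 1.60-fold lower (adjusted p = 0.0378); both were below background on the 2 Mequinenza arrays. These limits depend on the detection limit of each array. That of CUST_3524_PI415929191 is not strict, since the probe was well above background on 7 of the 8 other Ebro arrays. With 1 common floor for all arrays the calls were lost, with log2 differences of 0.43 for CUST_10688_PI415929191, 0.36 for CUST_11404_PI415929191, -0.66 for CUST_7267_PI415929191 and 0 for CUST_3524_PI415929191 (limma adjusted p = 0.498, 0.532, 0.480 and 1). In all, 8 probes of 7 sequences differed without the block, 6 higher and 2 lower, with 463 at an unadjusted p under 0.05. With the block there were 39 probes of 32 sequences, 25 higher and 14 lower, and 785 at an unadjusted p under 0.05. Of the 8 probes, 3 were well above background on neither Mequinenza array, 4 on no other Ebro array and 2 on all 12 arrays; of the 39 these were 6, 8 and 11. These include 1 of the 8 and 3 of the 39 that were well above background on no Ebro array, so their calls compare signals near background. With array weights no probe was called in either fit (smallest limma adjusted p 0.143 without and 0.0872 with the block; 270 and 347 probes at an unadjusted p under 0.05). AM230425 and AF508222, also chosen after their values were seen, each had 3 called probes with the block. The 3 probes of AM230425 were 3.56 to 5.54-fold higher at Mequinenza and well above background on all 12 arrays, but with the percentile over all probes 1 of its 4 tested probes was called. Of AF508222, CUST_52_PI415929188 and CUST_76_PI415929191 had log2 differences of 3.42 and 2.95 and were well above background on 3 and 5 of the 8 other Ebro arrays, and its remaining called probe was above background on none of these 8. Under normexp the log2 differences of AF508222 were 1.51 to 1.80.

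The split for Mequinenza also moved with the scaling. With the block it was 45 higher and 51 lower with the authors' values, 29 and 39 with the percentile over all probes and 21 and 2 under normexp. Without the block it was 4 and 3 under quantile normalization and 2 and 0 under normexp. Leaving out Mequinenza replicate 1 raised the count to 212 without the block, 52 higher and 160 lower, and to 491 with it, 234 higher and 257 lower, and leaving out Mequinenza replicate 2, the array with the lowest share of probes above background, gave 0 and 3. Without the block, leaving out Riba Roja replicate 2 gave 1 call and leaving out any other array of Riba Roja, Flix Reservoir, Flix Factory or Faio gave 0. With the block, leaving out an array of Riba Roja, Flix Reservoir or Flix Factory, or Faio replicate 2, gave between 3 and 6.

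No probe passed the threshold for Flix Factory, Flix Reservoir, Riba Roja or Faio against the other Ebro sites in the limma fit, with or without the block. At an unadjusted p under 0.05 there were 180 probes for Flix Factory, 118 for Flix Reservoir, 59 for Riba Roja and 221 for Faio without the block, and 376, 240, 216 and 518 with it. The median 95% confidence interval reached 0.93 on the log2 scale to either side of a difference without the block and 0.63 with it, before adjustment. After adjustment, 1.4% of the 2-fold changes in simulated data for Flix Factory were found without the block and 31.4% with it, and 43.6% and 83% of the 4-fold changes. The simulated arrays were equally noisy and had no other site difference, so these shares are not the power in the real arrays. For Faio the count of calls was 2 without and 17 with the block under quantile normalization, 5 and 16 with the authors' values, 0 and 8 with the percentile over all probes, 0 and 9 with a common floor or over the 2806 probes, 0 and 4 with limma-trend, and 3 and 2 with array weights. It was 3 in both fits with means per sequence, and 3 with the site as a random block. For Flix Factory it was 2 and 0 under quantile normalization or with the authors' values, 0 and 2 over the 2806 probes or with limma-trend, and 0 and 7 with array weights. Fits on the compared arrays alone gave 1 call in both fits for Flix Factory and for Flix Reservoir. Leaving out Mequinenza replicate 1 changed the counts for Flix Factory, Flix Reservoir, Riba Roja and Faio to 36, 23, 21 and 46 without the block and to 117, 83, 73 and 147 with it. Leaving out either Sitjar array gave 1 call for Flix Factory and 1 for Flix Reservoir in both fits, and leaving out Flix Reservoir replicate 1 gave 1 and 4 for Flix Reservoir. For Faio, leaving out Riba Roja replicate 2 gave 7 and 13, Mequinenza replicate 2 gave 5 and 9, and Faio replicate 1 gave 2 and 3.

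Flix Factory and Flix Reservoir, which share a place name, were also compared with each other. No probe passed the threshold in the limma fit without or with the block, with 72 (1.7%) and 188 (4.4%) probes at an unadjusted p under 0.05. Both shares lie below the 0.05 expected if no probe differed. The median 95% confidence interval reached 1.17 and 0.79 to either side. Leaving out Flix Reservoir replicate 1 gave 1 call without the block and 5 with it.

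RXR, the symbol of the retinoid X receptor, a nuclear receptor, was the only gene symbol on the array. It was represented by 6 probes, of which 2 passed the filter on signal. For CUST_2_PI415987745 the log2 difference was 0.09 (SE 0.33) between the Ebro sites and Sitjar and -0.52 (SE 0.33) between Flix Factory and the other Ebro sites, with limma adjusted p = 0.978 and 1.000. For CUST_3_PI415987745 the same differences were -0.05 (SE 0.51) and -0.31 (SE 0.52), with adjusted p = 0.992 and 1.000.

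The F tests asked whether expression differed anywhere among the sites. Without the block no probe passed the threshold among the 6 sites (332 at an unadjusted p under 0.05) or among the 5 Ebro sites (243). With the block, 3 probes differed among the 6 sites, and they are named here after their values were seen: CUST_4_PI415924929 and CUST_68_PI415929191 of AF508224 (adjusted p = 0.0286 and 0.0494) and CUST_8173_PI415929191 of EY435040 (adjusted p = 0.0286). CUST_4_PI415924929 also differed among the 5 Ebro sites (adjusted p = 0.0254). Its site means were -0.41 at Mequinenza, -2.62 at Faio, -2.54 at Riba Roja, -3.84 at Flix Reservoir, -4.07 at Flix Factory and -3.33 at Sitjar, on the scaled log2 scale. With the block, the 6-site count was 8 under normexp, 14 under quantile normalization, 48 with median scaling, 79 with the percentile over all probes, 100 with the authors' values, 78 with limma-trend, 41 over the 2806 probes, 6 with a common floor and 0 with array weights or no filter on dim probes; the 5-site count was 3, 9, 10, 0, 12, 7, 9, 8 and 0 in the same order. Without the block, quantile normalization gave 7 and 3 for the 6 and the 5 sites, the authors' values 11 and 7, and a common floor 1 and 1. Means per sequence gave 4 in both fits for the 6 sites, and 0 without and 5 with the block for the 5 sites. Fits on the Ebro arrays alone gave 1 and 3 for the 5 sites. The 6-site count was 147 without the block and 529 with it when Mequinenza replicate 1 was left out, 2 and 22 without Mequinenza replicate 2, and 2 and 2 without Faio replicate 1. Leaving out a Sitjar array gave 1 and 4, and leaving out any other array gave 0 in both fits. Among the 5 Ebro sites the counts were 129 and 290 without Mequinenza replicate 1, 2 and 4 without Mequinenza replicate 2 or Faio replicate 1, 1 and 3 without a Sitjar array, and 0 otherwise.

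The profile of each site, taken as its array minus the mean of the other arrays of the same slide over 2806 probes, was compared across the slides. Probes are not independent replicates, so the test permuted the sites. For Sitjar the correlation across probes between the 2 slides was 0.62, for Flix Factory 0.54, for Faio 0.40, for Flix Reservoir 0.32, for Mequinenza 0.31 and for Riba Roja 0.17. Their mean was 0.394, against -0.071 for arrays of different sites. Of the 720 ways to match the sites across slides, the true one gave the highest mean (one-sided exact permutation p = 0.00139, the smallest these matchings can give; highest other mean 0.374). Riba Roja on slide 1 correlated more with Flix Factory (0.322) and Flix Reservoir (0.235) on slide 2 than with itself, and Mequinenza on slide 2 correlated more with Faio on slide 1 (0.371) than with itself. Among the 5 Ebro sites alone the mean was 0.332, again the highest of 120 matchings (one-sided exact permutation p = 0.00833, the smallest possible; highest other mean 0.302). After Benjamini-Hochberg adjustment over these 2 tests, the permutation p-values were 0.00278 and 0.00833.

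**Figure D4:**
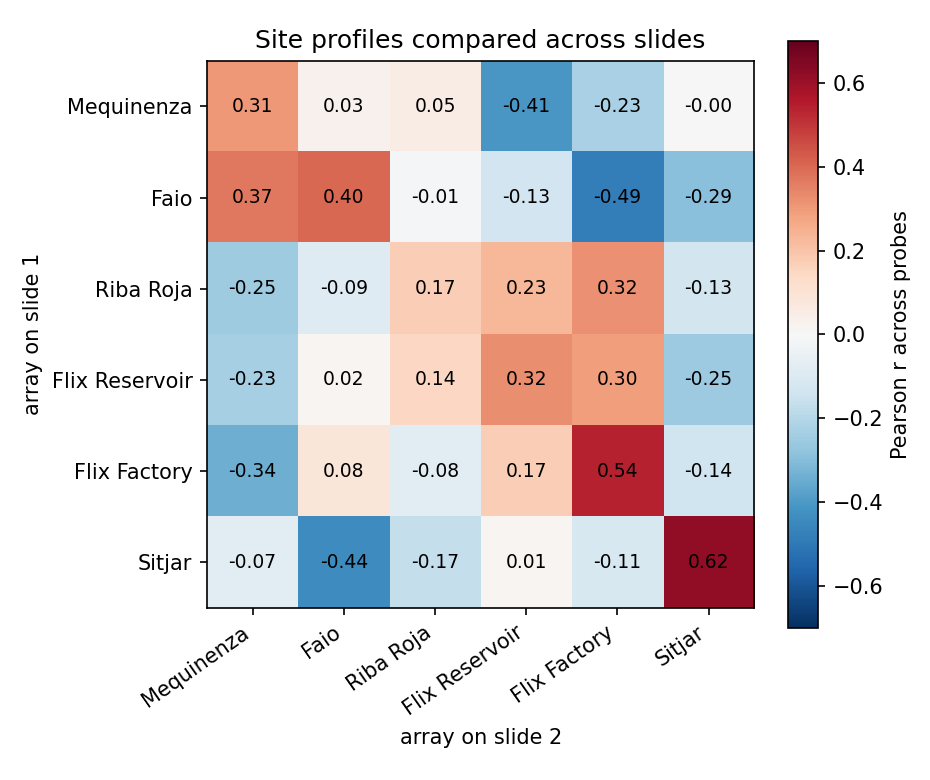
Pearson correlation across 2806 probes between the profile of each site on slide 1 (rows) and on slide 2 (columns), each profile being an array minus the mean of the other arrays of its slide; red is positive and blue negative. The diagonal holds the arrays of the same site, from 0.17 for Riba Roja to 0.62 for Sitjar.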

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

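The restriction of the scaling percentile to the 2806 probes, the common floor and every combination of the replicate block with another choice were chosen only after the data were seen. The percentile over all probes was listed as an alternative only then, although it lies closest to the design fixed beforehand. All other alternatives were planned. Because the replicate number and the slide coincide here, the replicate block is also the slide block. The gene list shifts, with their alternatives, were not run because the files pair no gene descriptions with the probes. Where an array was left out, the lone array of its site was assumed to vary like the other sites. In fits without the block its site then lay on 1 slide, so part of the slide difference entered the comparison. The cause of the changes below was not tested, except where fewer probes or arrays were tested by construction. Signal over background limits these results, since at most 34.8% of the probes were well above background on an array and 4305 were tested. For Ebro sites against Sitjar the median log2 difference of all tested probes was 0.05 as reported, -0.05 under quantile normalization, -0.06 with the authors' values or the percentile over all probes, and 0.31 under normexp, so splits into higher and lower probes are relative to those shifts. With no filter on dim probes, the median over all 13654 probes was 0.86.

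Counts of called probes follow, first without the block. Among the 6 sites the count was 0 as reported, 7 under quantile normalization, 11 with the authors' values, 1 with the common floor, 3 with the replicate block and 4 with means per sequence. Among the 5 Ebro sites it was 0 as reported, 3 under quantile normalization, 7 with the authors' values, and 1 each with the common floor, the replicate block or only the arrays compared. For Ebro sites against Sitjar it was 3 as reported, 1 each under normexp, the common floor and limma-trend, 7 under quantile normalization, 18 with the authors' values, 0 with no filter on dim probes or a threshold of 0.01, 15 over the 2806 probes above background on all arrays, 197 with the replicate block and 72 with the site as a random block. For Mequinenza it was 8 as reported, 2 each under normexp, limma-trend and the filter to 2806 probes, 4 with median scaling, 3 with the percentile over all probes, 13 with the common floor, 125 with no filter on dim probes, 39 with the replicate block, 325 with the site as a random block (77 higher and 248 lower, against 6 and 2 as reported), and 0 with array weights or a threshold of 0.01. For Faio it was 0 as reported, 2 under quantile normalization, 5 with the authors' values, and 3 each with array weights, means per sequence and the site as a random block. For Flix Factory it was 0 as reported, 2 each under quantile normalization and with the authors' values, and 1 with only the arrays compared; for Flix Reservoir it was 0, and 1 with only the arrays compared. The replicate block changed no other call or count by more than 1.5 times.

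With the replicate block, the count among the 6 sites was 3, and 8 under normexp, 14 under quantile normalization, 48 with median scaling, 100 with the authors' values, 41 over the 2806 probes, 79 with the percentile over all probes, 6 with the common floor, 78 with limma-trend, and 0 with no filter, array weights or a threshold of 0.01. Among the 5 Ebro sites it was 1, and 3 under normexp or with only the arrays compared, 9 under quantile normalization or over the 2806 probes, 10 with median scaling, 12 with the authors' values, 8 with the common floor, 7 with limma-trend, 5 with means per sequence, and 0 with no filter, the percentile over all probes, array weights or a threshold of 0.01. For Ebro sites against Sitjar it was 197, and 568 under normexp, 383 with median scaling, 299 with the authors' values, 408 over the 2806 probes, 442 with limma-trend, 85 of 1845 with means per sequence, 130 with a minimum of 2-fold, and 0 with no filter or a threshold of 0.01. Of the 197 probes, the number kept in the same direction was 163 under normexp, 121 under quantile normalization, 197 with median scaling, 140 with the authors' values and 131 with the percentile over all probes. For Mequinenza it was 39, and 23 under normexp, 59 with median scaling, 96 with the authors' values, 165 with no filter, 68 with the percentile over all probes, 22 with the common floor, 24 with means per sequence, 2 with a threshold of 0.01 and 0 with array weights. For Faio it was 0, and 17 under quantile normalization, 16 with the authors' values, 9 over the 2806 probes or with the common floor, 8 with the percentile over all probes, 4 with limma-trend, 2 with array weights and 3 with means per sequence. For Flix Factory it was 0, and 2 over the 2806 probes or with limma-trend, 7 with array weights and 1 with only the arrays compared; for Flix Reservoir it was 0, and 1 with only the arrays compared.

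Leaving out each array in turn gave 0 to 147 calls among the 6 sites, 0 to 129 among the 5 Ebro sites, 0 to 102 for Ebro sites against Sitjar, 0 to 36 for Flix Factory, 0 to 23 for Flix Reservoir, 0 to 21 for Riba Roja, 0 to 46 for Faio, 0 to 212 for Mequinenza and 0 to 1 for Flix Factory against Flix Reservoir. With the replicate block the ranges were 0 to 529, 0 to 290, 0 to 800, 0 to 117, 0 to 83, 0 to 73, 0 to 147, 3 to 491 and 0 to 5, in the same order. The highest values came without Mequinenza replicate 1, except for Flix Factory against Flix Reservoir, where they came without Flix Reservoir replicate 1.

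The 7 probes named by the rule had 164 values under these alternatives. Some alternatives, such as the block, limma-trend, array weights or no filter on dim probes, left the log2 difference itself unchanged. The direction could not change there. None changed direction, 66 kept their call and 98 lost it; 1 of those, CUST_3524_PI415929191 with the common floor, was 0 because all 10 Ebro arrays lay at the floor. With the percentile over all probes, CUST_11632_PI415929191, CUST_10688_PI415929191 and CUST_3524_PI415929191 were not called (limma adjusted p = 0.0782, 0.0679 and 0.0753). Some lost calls came with far smaller differences. Under normexp the log2 difference was -0.11 for CUST_8173_PI415929191 (-2.74 as reported), -0.09 for CUST_3524_PI415929191 (-1.86), 1.08 for CUST_10688_PI415929191 (3.74) and CUST_11404_PI415929191 (3.69), -0.88 for CUST_7267_PI415929191 (-2.83) and 1.45 for CUST_11632_PI415929191 (2.26). With the common floor it was 0.43 for CUST_10688_PI415929191, 0.36 for CUST_11404_PI415929191 and -0.66 for CUST_7267_PI415929191, all smaller than the lower limits reported, which use the lowest signal well above background on each array. CUST_1825_PI415929191 kept its call in 16 of 24 alternatives. CUST_8173_PI415929191 and CUST_11632_PI415929191 kept theirs in 8 each, and had no value with the common floor, where all arrays of these probes lay at the floor. The agreement of site profiles across the slides was 0.394 under quantile normalization and 0.397 with the authors' values for the 6 sites, and 0.332 and 0.333 for the 5 Ebro sites.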

Other observations

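The tests of the chance matching of sites, of the shared row of the slide and of the Mequinenza probes by slide and by partner array were chosen only after the results they bear on were seen, as were the sequences named here. Further sequences with several called probes set Mequinenza apart from the other Ebro sites when the slide was a block. EY434180 had 4 tested probes, all higher at Mequinenza, with log2 differences of 2.22 to 2.78; 2 of them passed the threshold, and 1 did under quantile normalization or with the percentile over all probes. All 4 kept their direction under 5 other scalings, with log2 differences of 1.42 to 1.85 under normexp. AJ517599 was lower by 2 of its 3 tested probes, by 2.39-fold for CUST_11653_PI415929191 and 2.23-fold for CUST_7778_PI415929188 (limma adjusted p = 0.0480 and 0.0382), and 0 of the 3 were called under quantile normalization, with log2 differences of -0.73 to -2.27, or under normexp, with -0.13 to -0.57, against -0.80 to -1.26 as reported. Both called probes were well above background on 1 of the 2 Mequinenza arrays, so their folds rest partly on signal near background.

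The calls between the Ebro sites and Sitjar with the slide as a block were set against 2 technical explanations. A sequence variant under a single probe could change its binding in one population without a change in expression, and would leave other probes of the same sequence unmoved. For the 162 of 197 called probes (107 sequences) with another tested probe of the same sequence, the mean change of those others was 0.895 of the called probe's own change (median over called probes, 95% bootstrap interval 0.827 to 0.921). Of the 376 pairs of a called and another probe, 361 (96.0%) had the same sign, against 73.9% in sequences without a call. This argues against single-probe variants as the main source for these 162 probes, with 2 limits. In 40 sequences at least 2 probes were called, so some of the other probes were themselves called and count from both sides. The sequences without a call were not matched for the size of their change, so 73.9% is not a like comparison. The explanation stays open for the called probes without another tested probe. Overlapping probes that share a variant, or 2 variants in a sequence, also stay open because probe positions were not used. Sitjar had the highest 75th percentile of signal on slides 1 and 2 (71153.4 and 40352.5, next highest 54705.6 and 32379), so overall signal ran with this contrast. Quantile normalization gives all arrays the same distribution of signal. Under it, 121 of the 197 calls (61.4%) were kept in the same direction, although the split into higher and lower probes moved. The values as reported had already been scaled by the 75th percentile of each array, so this could not test a uniform shift. It bears on the shape of the distribution, which was not the only source of the 121 calls kept. Effects of array brightness that differ between probes stay open. Position on the slide stays open, since Sitjar had the same position on both slides, and a biological difference between the populations is a hypothesis that the data do not test apart from it.

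The calls at Mequinenza with the slide as a block could come from its second array alone, which had the lowest share of probes above background; the first array would then show little of the differences. For the 11 called probes well above background on all 12 arrays, the difference from the other Ebro sites on slide 1 was 1.022 of that on slide 2 (median, 95% bootstrap interval 0.824 to 1.087), and on slide 1 it was 1.01 to 3.01 on the log2 scale in the called direction. For 9 other called probes, whose slide 1 signals all lay above a common floor of the slide, the ratio was 0.815 (95% bootstrap interval 0.779 to 1.038), with slide 1 differences of 0.93 to 2.21; the slide 2 side of this ratio rests on signals near background. Calls favour probes whose 2 arrays agree, so agreement was also counted without regard to calls. Of the 2806 probes, 60 were at least 2-fold apart in the same direction on both Mequinenza arrays, against 9.5 expected if the arrays were unrelated. The 2 ratios were taken over called probes, so they cannot decide. The count does not rest on calls, but it covers only probes well above background on all 12 arrays. These include the 11 called probes and not the 9. For such probes as a set, the count argues against the second array as the only source, within the limit given below for Faio. For the 9 calls that explanation stays open.

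The agreement was not limited to the 2 Mequinenza arrays. With Faio on slide 1 in place of Mequinenza, the same count was 88 against 19.8 expected, and with each of the other 3 Ebro sites it was 1 to 6. When the 2 labels on slide 1 were exchanged in this way, limma called 0 probes in both fits for each of the 4 partners, against 8 without and 39 with the block for the real pairing. At an unadjusted p under 0.05, however, Faio as partner gave 482 and 1121 probes, more than the 463 and 785 of the real pairing, and the other partners 155 to 351. An influence or a likeness shared by the second Mequinenza array and the first Faio array therefore stays open. The remaining 19 called probes had slide 1 signals under the floor. Their ratio was 0.917 as measured (95% bootstrap interval 0.813 to 1.036, 18 probes with a value on both slides) and 0.422 with slide 1 raised to the floor (0.012 to 0.791). For these 19 probes a difference of the population and an effect of the dim array cannot be told apart, because the ratio depends on signals under the floor. The set of 9 was parted from these 19 after the ratio of all 28 with the floor, 0.659 (0.404 to 0.877), had been seen.

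Without the second Mequinenza array the 4 probes named by the rule lost their calls, with a single array left at the site. Their log2 differences without the block were 2.61 for CUST_10688_PI415929191 (3.74 as reported), 3.04 for CUST_11404_PI415929191 (3.69), -2.90 for CUST_7267_PI415929191 (-2.83) and -1.86 for CUST_3524_PI415929191 (-1.86). These hold part of the slide difference, since the array left lay on slide 1. With the block, 491 probes were called without the first array and 3 without the second. Most of the 491 were weak on the first array: in the called direction, the median log2 difference on slide 1 was -0.021 for the 234 higher and 0.229 for the 257 lower probes, against 1.38 and 2.36 on slide 2. Array weights left 0 calls in both fits (smallest limma adjusted p 0.143 without and 0.0872 with the block; 270 and 347 probes at an unadjusted p under 0.05). Over all 2806 probes, the correlation of Mequinenza across the slides among the Ebro sites was 0.338, against 0.349 for Faio on slide 1 with Mequinenza on slide 2, a difference of -0.0105 (95% bootstrap interval -0.074 to 0.053), which does not decide for the profile as a whole. Position on the slide, the same on both slides, and a difference of the population stay open.

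On average over sites, though not for each site, the arrays of a site resembled each other across slides more than chance matching would give. Only 1 of the 720 matchings of 6 sites, the true one, reached a mean correlation of 0.394 (highest other 0.374), and only 1 of the 120 matchings of the 5 Ebro sites reached 0.332 (highest other 0.302). Chance matching alone is therefore unlikely for the mean, although this test was chosen after the values were seen and the 5 sites are among the 6. The same site gave the highest correlation of its row and column for 4 of the 6 sites and for 2 of the 5 Ebro sites; the exceptions include Riba Roja on slide 1, which correlated more with Flix Factory (0.322) and Flix Reservoir (0.235) on slide 2 than with Riba Roja (0.170). Array position may give the same agreement, because each site kept its position: positive control probes, which hold no mussel RNA, had a mean matched correlation of -0.319 across the slides (95% bootstrap interval -0.392 to 0.222; 618 of 720 matchings as high), but only 10 such probes could be used and the interval is too wide to decide. Riba Roja, Flix Reservoir and Flix Factory, which shared a row of the slide, were the closest sites (root mean square log2 differences 0.309 between Riba Roja and Flix Reservoir, 0.402 between Flix Reservoir and Flix Factory, and 0.417 between Riba Roja and Flix Factory). In the other row, the sites were farther from each other than from the first row by 0.0718 with Sitjar included (95% bootstrap interval 0.037 to 0.101). Among the Ebro sites alone, the single pair of that row, Mequinenza and Faio, was closer (0.568) than the pairs across rows (0.616), a difference of -0.048 (95% bootstrap interval -0.091 to -0.007). Both intervals resampled sequences on the same arrays, so neither holds the spread between pools. An effect of the row and a likeness of the 3 populations therefore cannot be told apart.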
